A study of Mus musculus with 19 samples.

How the data were processed

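Bulk RNA sequencing covered 7 adult libraries (3 of wild-type stem cells, 2 of regenerating crypt cells, 2 of Ascl2-deleted stem cells) and 8 libraries of Epcam-positive hindgut epithelium (2 each at E11, E12, E14 and E16). Single-cell RNA sequencing covered 1 library of regenerating cells on day 8. Per the labels, adult cells came from mice of mixed C57BL/6 and 129/Sv background and were made into libraries with a SMARTer low-input kit, and hindgut cells came from CD1 embryos and a SMART-Seq v4 kit; the 2 sets were therefore fitted separately. Wild-type and regenerating cells carried the Ascl2 mCherry reporter and an Lgr5 allele with the diphtheria toxin receptor and GFP, and knockout cells a floxed Ascl2 and an Lgr5 allele with GFP and Cre, so genotype, allele and sort differ together. Tamoxifen is given for the knockout libraries only and differs with them. The 3 ChIP-seq libraries of the series were not analysed here.

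The deposited bulk table holds raw read counts per gene symbol, which the submitters' processing notes attribute to STAR 2.5.3a and HTSeq, with GRCm38 and mm10 as builds; annotation release and strand setting are not stated. Of 24062 genes, 22550 (93.7%) matched the RefSeq table that gave the coordinates. Another 5 entries of the table name no gene and count reads without a feature, ambiguous, of low quality, not aligned or not unique; they were used only to describe the libraries. The deposited single-cell matrix holds UMI counts per gene and droplet for all barcodes, from Cell Ranger 3.0.2 per the file headers. Whole numbers, library totals and replicate differences of both tables were checked.

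Counts assigned to genes ranged from 13826958 to 30583908 per bulk library. Genes with low counts were removed with filterByExpr by group, libraries were scaled with TMM, and genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. All 7 adult libraries entered 1 fit and all 8 hindgut libraries another, with group as the term, so that groups of 2 share an estimate of spread (common biological coefficient of variation 0.513 in adult and 0.310 in hindgut libraries). The comparisons were regenerating against wild type, knockout against wild type, knockout against regenerating, E16 against E11, the 3 steps between neighbouring ages, and an F test over the 4 ages. Levels are CPM on the TMM scale. Transcripts tied to sex differed between adult libraries. Xist, a transcript of female cells, was at 0.0299 and 0.0322 CPM in the regenerating and 28.5, 0.292 and 18.2 CPM in the wild-type libraries. Ddx3y, on the Y chromosome, was at 31.8 and 24.3 CPM against 0, 13.1 and 12.8. In knockout replicates 1 and 2 Xist was at 49.997 and 0.0916 CPM and Ddx3y at 0.453 and 25.02 CPM. No fit had a term for sex. A fold change against a group without counts is a lower bound computed at a floor of 3 counts over the group, and one against 1 to 3 counts is a ratio with its 95% counting interval. In simulated counts with the same depths and spread, the fits recovered 2 to 4 of 100 genes changed 2-fold and 43 to 64 of 100 changed 4-fold in the adult comparisons, and 31 to 37 and 61 to 84 in the hindgut comparisons, with 5 to 9 unchanged genes called. In regenerating against wild type 9 unchanged genes were called beside 4 and 64 recovered, a share above the threshold of 0.05. The same held for knockout against wild type (8 beside 4 and 50) and against regenerating cells (9 beside 2 and 43).

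The choices of groups, tests, lists and first alternatives were made before the data were examined. The 25 gene lists were stem cell, Wnt target, reserve stem cell, replication, mitosis, absorptive colonocyte, goblet, deep crypt secretory, enteroendocrine, tuft, fetal-like repair, YAP target, interleukin 11 and gp130, Notch, interferon response, MHC class II, immediate-early, p53 target, oncofetal, posterior patterning, endoderm identity, immune cell, stromal cell, endothelial cell and neural cell genes; a red cell list was read as levels only. Muc3, Clca4a and Sh2d6 matched no symbol, and Ccn1 and Ccn2 were found as Cyr61 and Ctgf. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 25 lists of a comparison, with an estimated correlation and with fry beside it. For the embryonic sets, the 200 genes with the smallest p on each side of E16 against E11 (threshold 0.05, at least 2-fold, tested in the adult fit; 1921 and 2953 genes qualified) were tested the same way in the adult comparisons. The sets share 2 genes with the replication and mitosis lists, 1 with the stromal and 2 with the immune list.

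Genes to follow singly, not all of them named, were chosen by rule: always Ascl2, Lgr5, Il11ra1 and Ly6a; in the 4 pairwise comparisons the 6 largest rises and 6 largest falls by fitted log2 fold change among called genes at 10 CPM or more in the higher group with no overlap between groups, leaving out predicted, ribosomal and mitochondrial genes and receptor segments; from each list with a called member or a passing test up to 4 members with the smallest adjusted p; and in the hindgut steps the 3 genes with the smallest adjusted p per direction.

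Droplets were called cells at 0.1 of the 99th percentile of UMIs among the 5000 largest droplets, and cells were kept with at least 500 genes and at most 20% mitochondrial UMIs. Doublets were scored with scrublet at an expected rate of 0.05, and 2 were removed, leaving 3251 cells with 6796 to 129845 UMIs. With scanpy 1.11.5 in Python 3.11.15, 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 0.8 gave 13 clusters, each named from the fixed lists by markers raised at least 1.5-fold. Levels are CPM of summed UMIs with exact Poisson intervals, shares have exact Clopper-Pearson intervals, and 71722 droplets of 10 to 100 UMIs served as empty droplets. Genes that changed in bulk were placed by the class with the highest level and compared with 10000 random lists matched in 10 expression bins.

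Alternatives were DESeq2 1.42.0, upper-quartile factors, no filter, a filter of 5 CPM in 2 libraries, the replicate number as a block, only the 2 groups compared, all 15 libraries in 1 fit, leaving out each library, set sizes of 100 and 500, sets without cell cycle genes, and other droplet, mitochondrial, doublet and clustering settings. Chosen after seeing the data were library size scaling, offsets that remove each library's trend of counts against genomic span, fits without the E16 libraries, hindgut sets without ribosomal protein, oxidative phosphorylation and histone genes, single-cell shares without mixed clusters, and 8 more lists (neutrophil, germ cell, nephric, basal squamous, ribosomal protein, oxidative phosphorylation, histone and chaperonin genes).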

Results

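RNA sequencing covered 15 libraries from mouse colon and embryonic hindgut, and droplet single-cell sequencing covered 1 library. In adult mice, colonic crypt cells were sorted on an Ascl2-mCherry or a GFP reporter. Ascl2 is a transcription factor of crypt base stem cells (chromosome 7, 142966822 to 142969264 in GRCm38). The adult groups were resting wild-type stem cells (3 libraries), crypt cells regenerating after the Lgr5-positive stem cells had been killed with diphtheria toxin (50 ug/kg, 4 injections; 2 libraries), and stem cells with Ascl2 deleted by tamoxifen (2 mg on days 1 and 2, then 1 mg; 2 libraries). The hindgut libraries held Epcam-positive epithelium at embryonic days E11, E12, E14 and E16, with 2 libraries per age. The single-cell library held cells positive for mCherry and negative for GFP on day 8 of regeneration and had no replicate. Counts assigned to genes came to 27237804, 26013572 and 26217842 in wild-type replicates 1 to 3, 30074569 and 28071012 in the regenerating libraries, and 17926856 and 16553279 in the knockout libraries. They came to 26693704 and 30583908 at E11, 26810809 and 28371546 at E12, 22605165 and 23685904 at E14, and 16861928 and 13826958 at E16. Levels below are CPM (read counts scaled to a common library total) on the TMM scale, as mean ± SD, with n = 3 for wild type and n = 2 for every other group. Intervals and floors cover counting error only. Every named gene that passed a test had all libraries of 1 group above all libraries of the other, unless stated.

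The comparison of regenerating with wild-type cells asks how cells that refill the crypt after stem cell loss differ from resident stem cells. Some markers of goblet and deep crypt secretory cells rose, in both regenerating libraries, while the list of tuft genes lay lower. Reg4, a marker of deep crypt secretory cells, stood at 11754 ± 3624 CPM against 464 ± 209, and Spink4, a goblet cell peptide, at 13326 ± 4210.1 CPM against 910.1 ± 489. Spdef, a transcription factor of goblet cell maturation, stood at 430.0 ± 219.8 CPM against 62.9 ± 17.3. Among the few genes that fell was the stem cell marker Smoc2, at 95.7 ± 19.8 CPM against 314 ± 44.0. The plot of CPM per adult library shows these genes.

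Of 13911 genes tested, edgeR called 46, with 42 up and 4 down in regenerating cells, each changed at least 2-fold; 1460 had an unadjusted p below 0.05. DESeq2 called 470 (289 up, 181 down), which included all 46. Reg4 (chromosome 3, 98222138 to 98236748) had a log2 fold change 4.66 ± 0.47 (SE), adjusted p = 0.0124. Spink4 (chromosome 4, 40920056 to 40931395) had a log2 fold change 3.87 ± 0.49 (SE), adjusted p = 0.0204, and Spdef (chromosome 17, 27714446 to 27731003) a log2 fold change 2.77 ± 0.35 (SE), adjusted p = 0.0203. The other large rises were St6galnac1, a sialyltransferase of mucin glycans (6.81, adjusted p = 0.0341), the chymase Cma1 (6.50, 0.0124), the Notch-family ligand Dlk1 (6.05, 0.0204) and the matricellular gene Nov (4.65, 0.0124). Among the 4 genes that fell were Smoc2 (-1.71, adjusted p = 0.0204), the transcription factor Sox4 (-1.52, 0.0223) and Clca4 (-1.74, 0.0221). Without wild-type replicate 1 or regenerating replicate 2, only 1 gene was called in each case; without knockout replicate 1 or 2, which share the estimate of spread, 20 and 17 were called. Each of the 14 calls followed singly was lost without at least 1 library. By library, 13 of them were lost without wild-type replicate 1, 6 without replicate 2 and 6 without replicate 3. Without regenerating replicates 1 and 2 it was 7 and 13, and without either knockout replicate 9. Transcripts tied to sex differed between the adult libraries, so sex was not separated from group or from the spread between replicates in these calls. Library size scaling shifted the median of all genes by -0.18 and offsets for genomic span by -0.15 on the log2 scale.

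Ascl2 stood at 71.4 ± 20.3 CPM against 122 ± 25.8, lower in both regenerating libraries than in any wild-type library, without passing the test (log2 fold change -0.77 ± 0.26 (SE), adjusted p = 0.316, 0.0965 to 0.948 over 15 alternatives). Lgr5, the receptor that marks the ablated stem cells (chromosome 10, 115450314 to 115587780), stood at 4.49 ± 3.81 CPM against 41.1 ± 12.8 (log2 fold change -3.20 ± 0.69 (SE), adjusted p = 0.125, 2.86e-05 to 0.428 over 15 alternatives). It passed with DESeq2, at an adjusted p of 2.86e-05. Il11ra1, the receptor subunit for interleukin 11 (chromosome 4, 41760443 to 41769473), stood at 31.6 ± 3.76 CPM against 8.86 ± 4.78 and also lay outside the wild-type range (log2 fold change 1.83 ± 0.54 (SE), adjusted p = 0.249, 0.0411 to 0.866 over 15 alternatives); DESeq2 gave 0.0411. Ly6a, the Sca-1 antigen of repairing epithelium (chromosome 15, 74994877 to 74998031), stood at 327 ± 79.1 CPM against 311 ± 240.1 with overlapping groups; its log2 fold change of 0.07 flipped to -0.09 under library size scaling and -0.13 with offsets for span. Directions of all other genes named in the adult comparisons held under each scaling tried, unless stated.

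Of 25 gene lists fixed before the data were examined, 9 passed the list test (camera). Of 20 goblet genes, 3 rose and none fell (13 up adjusted over the list alone). The goblet list had a median log2 fold change of 1.57 (adjusted p = 5.73e-21), with adjusted p = 0.211 with an estimated correlation and 2.02e-21 to 0.211 over 12 alternatives. Of 7 deep crypt secretory genes, which share Spink4 and Agr2 with the goblet list, 4 rose (6 up adjusted over the list alone). The deep crypt secretory list had a median log2 fold change of 2.496 (adjusted p = 1.39e-20), with adjusted p = 0.0912 with an estimated correlation and 1.96e-20 to 0.0912 over 12 alternatives. Of 20 stem cell genes, Smoc2 fell (1 up, 2 down adjusted over the list alone). The stem cell list had a median log2 fold change of -0.25 (adjusted p = 0.000173), with adjusted p = 0.385 with an estimated correlation and 2.68e-05 to 0.385 over 12 alternatives. The Wnt target list, which shares 7 genes with the stem cell list, had no called member among 17 (1 down adjusted over the list alone). The Wnt target list had a median log2 fold change of -0.27 (adjusted p = 0.00502), with adjusted p = 0.508 with an estimated correlation and 0.000916 to 0.508 over 12 alternatives. Of 14 tuft cell genes 1 fell (10 down adjusted over the list alone). The tuft list had a median log2 fold change of -3.25 (adjusted p = 2.08e-19), with adjusted p = 0.0415 with an estimated correlation and 1.72e-19 to 0.0415 over 12 alternatives. Trpm5, the taste-signalling channel of tuft cells, was at 0.242 ± 0.250 CPM against 11.8 ± 5.18 (adjusted p = 0.0827). No absorptive colonocyte gene of 26 passed alone (2 down adjusted over the list alone). The colonocyte list had a median log2 fold change of -1.44 (adjusted p = 8.84e-09), with adjusted p = 0.508 with an estimated correlation and 1.86e-19 to 0.508 over 12 alternatives. None of 26 mitosis genes passed (none adjusted over the list alone). The mitosis list had a median log2 fold change of -0.37 (adjusted p = 2.01e-05), with adjusted p = 0.518 with an estimated correlation and 1.67e-10 to 0.518 over 12 alternatives. None of 21 enteroendocrine genes passed (none adjusted over the list alone). The enteroendocrine list had a median log2 fold change of -1.10 (adjusted p = 0.000843), with adjusted p = 0.385 with an estimated correlation and 2.95e-05 to 0.385 over 12 alternatives. Pyy, the peptide YY hormone, was at 12.1 ± 11.2 CPM against 33.5 ± 6.41 (adjusted p = 0.350).

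Markers of another cell type moved as well. Of 13 stromal genes, the proteoglycan Lum rose by at least 67.0-fold (5 up adjusted over the list alone). The stromal list had a median log2 fold change of 3.12 (adjusted p = 8.84e-09), with adjusted p = 0.0912 with an estimated correlation and 1.24e-11 to 0.0912 over 12 alternatives. The median was 2.08 with the 5 all-0 genes at their bound of 3 counts over the group. Summed stromal CPM nevertheless stayed low, at 19.4 ± 2.78 against 6.32 ± 1.87. The remaining 16 lists had adjusted p values from 0.0535 (neural cell, median 3.13, or 3.09 at the bounds) to 0.969. Among them were interleukin 11 and gp130 signalling (0.361), fetal-like repair (0.132), replication (0.507), oncofetal genes (0.759, median -0.32 but mean 0.86), YAP targets (0.683, median -0.24 but mean 0.83 and test up), p53 targets (0.969, median -0.02 but mean 0.05) and reserve stem cells (0.969, median 0.04 but test down). Leaving out 1 library ended the call of Wnt targets (0.139 without wild-type replicate 2), mitosis (0.107) and enteroendocrine genes (0.0699, both without regenerating replicate 2). It brought other lists past the threshold: interferon response (5.38e-05), MHC class II (0.0129), immediate-early genes (1.74e-05) and immune cells (0.000137) without wild-type replicate 2, and replication (0.0338) and fetal-like repair (0.0393) without wild-type replicate 3. Replication also passed without regenerating replicate 1 (0.000456), and neural cells without wild-type replicate 1 (0.0383), regenerating replicate 2 (0.0222), knockout replicate 1 (0.0102) or knockout replicate 2 (0.0109).

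The comparison of Ascl2-deleted with wild-type cells asks which genes depend on Ascl2 in colonic stem cells. Ascl2 itself was at 53.8 and 59.2 CPM in the 2 knockout libraries and at 109.7, 151 and 104 CPM in the 3 wild-type libraries (log2 fold change -1.11 ± 0.27 (SE), adjusted p = 0.0115). Transcript was thus still detected, and the labels do not say which part of the gene the floxed allele removes. Some stem cell genes fell with it. Lgr5 stood at 6.99 ± 4.63 CPM against 41.1 ± 12.8, Smoc2 at 70.1 ± 0.390 CPM against 314 ± 44.0 and the ephrin receptor Ephb3 at 16.3 ± 0.253 CPM against 92.5 ± 9.42. Lists of differentiated lineages did not pass upward, but single genes of such cells rose, such as the hormone Pyy (1639 ± 262 CPM against 33.5 ± 6.41) and the goblet peptide Spink4 (13497 ± 6327 CPM against 910.1 ± 489). Guca2a, which encodes guanylin, stood at 11103 ± 334 CPM against 1254 ± 1075.

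edgeR called 5039 of 13911 genes (36.2%), 2618 up and 2421 down, of which 4456 changed at least 2-fold. Scaling set the split: by library size alone 6561 genes were called, 1233 up and 5328 down (18.8% up instead of 52.0%), with the median of all genes shifted by -0.98 on the log2 scale, and 3654 calls were shared in the same direction. In both knockout libraries 51.2 and 51.4% of reads aligned to several places, against 39.1 to 40.2% in wild type, and the TMM factors were 0.616 to 0.660 against 1.21 to 1.32. The number of calls was 3413 without knockout replicate 1. Ascl2 lost its call without knockout replicate 1 (adjusted p = 0.0780) or 2 (0.0544), with a range of 0.000595 to 0.0780 over 16 alternatives; Lgr5 (log2 fold change -2.56 ± 0.67 (SE), adjusted p = 0.0168, 0.000232 to 0.110 over 16 alternatives) lost it without knockout replicate 1 (0.110). Ly6a stood at 1864 ± 1449 CPM against 311 ± 240.1 (log2 fold change 2.58 ± 0.84 (SE), adjusted p = 0.0402, 0.00189 to 0.337 over 16 alternatives). Its call was lost without wild-type replicate 3 (0.0723), regenerating replicate 1 (0.0539) or 2 (0.0651), or knockout replicate 1 (0.337), by library size scaling (0.139) and with offsets for span (0.179). Il11ra1 was at 7.67 ± 4.31 CPM against 8.86 ± 4.78 (adjusted p = 0.803, 0.133 to 0.914 over 16 alternatives). Of 95 calls followed singly, 57 kept the call whichever library was left out, and the genes named in the next paragraphs are among these unless stated.

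Of 20 stem cell genes, 12 fell and 2 rose (13 down and 2 up adjusted over the list alone). The stem cell list had a median log2 fold change of -1.35 (adjusted p = 0.00356), with adjusted p = 0.776 with an estimated correlation and 0.000626 to 0.776 over 12 alternatives. Ephb3 (chromosome 16, 21204620 to 21223309) had a log2 fold change -2.50 ± 0.24 (SE), adjusted p = 0.000109, Smoc2 (chromosome 17, 14279490 to 14404790) a log2 fold change of -2.16 (adjusted p = 0.000199) and Cdca7, a MYC target, of -2.95 (0.000228). Phlda1 went the other way (2.41, 0.000442). Of 17 Wnt targets, 8 fell and 1 rose (the same numbers adjusted over the list alone). The Wnt target list had a median log2 fold change of -1.17 (adjusted p = 0.0362), with adjusted p = 0.878 with an estimated correlation and 0.00594 to 0.878 over 12 alternatives. Myc fell (-2.40, 0.000648) and so did the Wnt effector Tcf7 (-3.04, 0.00317), and the cyclin gene Ccnd2 rose (1.31, 0.00128). The stem cell list lost its call without knockout replicate 2 (0.0557), and the Wnt list without wild-type replicate 2 (0.0749), knockout replicate 1 (0.0508) or knockout replicate 2 (0.160). Of 12 endoderm identity genes, 7 fell and 2 rose (the same adjusted over the list alone; adjusted p = 0.134). Hnf4a fell (-1.47, 0.00388), and the cytokeratin gene Krt19 rose (0.98, 0.00630) but by library size was at -0.0044. The intestinal homeobox genes Cdx1 (-1.39, 0.00107) and Cdx2 (-2.17, 0.00431) fell, as did Stat3, a transducer of gp130 signals (-1.23, 0.00367).

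Among differentiated lineages, 5 of 21 enteroendocrine genes rose and none fell (the same adjusted over the list alone). The enteroendocrine list had a median log2 fold change of 1.46 (adjusted p = 0.0968), with adjusted p = 0.954 with an estimated correlation and 0.00353 to 0.954 over 12 alternatives. Pyy (chromosome 11, 102106676 to 102107832) had a log2 fold change 5.61 ± 0.56 (SE), adjusted p = 0.000135, with every knockout library above every wild-type library, and Insl5, another hormone of colonic endocrine cells, a log2 fold change 5.17 ± 0.72 (SE), adjusted p = 0.000692. Of 20 goblet genes 6 rose and 3 fell (the same adjusted over the list alone). The goblet list had a median log2 fold change of 0.51 (adjusted p = 0.353), with adjusted p = 0.954 with an estimated correlation and 0.118 to 0.954 over 12 alternatives. Agr2 (2.80, 0.000153), Spink4 (3.89, 0.000414) and the trefoil peptide Tff3 (3.48, 0.00183) were among the rises. By library size the list median flipped to -0.44. Of 7 deep crypt secretory genes 3 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.353), with the median of 0.89 at -0.03 by library size. Of 14 tuft cell genes 6 fell (6 adjusted over the list alone). The tuft list had a median log2 fold change of -2.32 (adjusted p = 0.0554), with adjusted p = 0.776 with an estimated correlation and 0.00908 to 0.776 over 12 alternatives. Avil (-4.80, 0.00229) and Trpm5 (-5.40, 0.00486) were 2 of the falls. Of 17 fetal-like repair genes 7 rose (7 up and 1 down adjusted over the list alone). The fetal-like repair list had a median log2 fold change of 1.08 (adjusted p = 0.0753), with adjusted p = 0.776 with an estimated correlation and 0.0210 to 0.776 over 12 alternatives. S100a6 (10842 ± 3726 CPM against 735 ± 239) and the growth factor Areg (1439 ± 322 CPM against 75.7 ± 43.3) were 2 of the rises. Leaving out 1 library brought these lists past the threshold. Enteroendocrine genes passed without wild-type replicate 3 (0.0346) or regenerating replicate 1 (0.0450) or 2 (0.0212). Tuft genes passed without wild-type replicate 1 (0.0275) or 3 (0.0418), regenerating replicate 1 (0.00908) or 2 (0.0140), or knockout replicate 1 (0.0154). Fetal-like repair genes passed without wild-type replicate 1 (0.0271) or 3 (0.0346) or knockout replicate 1 (0.0499).

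The cell cycle lists split. Of 24 replication genes 11 fell and 4 rose (12 and 4 adjusted over the list alone; adjusted p = 0.134, 0.0247 without wild-type replicate 3). Of 26 mitosis genes 6 fell and 5 rose (7 and 6 adjusted over the list alone; adjusted p = 0.524). The kinesin gene Kif20a fell (-3.48, 0.000122), and Birc5, which encodes survivin, rose (1.85, 0.000898). The cell cycle inhibitor Cdkn1a rose (2.76, 0.00188), as did the apoptosis gene Bax (1.70, 0.000249), while 2 of 15 p53 targets fell (adjusted p = 0.922 for the list). The chemokine Cxcl10 rose (4.79, 0.000626). Of 22 interferon response genes 3 rose and 1 fell (adjusted p = 0.954; median -0.61 but test up). The other lists did not pass, with the same counts adjusted over the list alone. They were absorptive colonocyte (4 up and 4 down of 26, 0.893), reserve stem cell (1 and 1 of 6, 0.535), and YAP targets (3 and 1 of 19, 0.666), then interleukin 11 and gp130 (1 down of 9, 0.514), Notch (1 up and 2 down of 12, 0.514) and MHC class II (none of 8, 0.922). Further ones were immediate-early genes (3 up of 16, 0.331, 0.00795 without wild-type replicate 2), oncofetal (2 and 2 of 9, 0.922, median 0.89 but test down), posterior patterning (2 up and 3 down of 16, 0.893, median 0.30 but mean -0.32) and neural cell (2 up of 6, 0.791). By library size the medians of YAP targets (-0.61), immediate-early genes (-0.63), p53 targets (-0.89), oncofetal (-0.07) and posterior patterning genes (-0.69) turned negative.

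Transcripts of cells other than epithelium were also higher in both knockout libraries. Of 13 stromal genes 11 rose (11 adjusted over the list alone). The stromal list had a median log2 fold change of 7.51 (adjusted p = 6.27e-05), with adjusted p = 0.776 with an estimated correlation and 9.50e-08 to 0.776 over 12 alternatives. The median was 6.80 with all-0 genes at their bound. The matrix genes Mgp (32.0 ± 14.8 CPM against 0.0599 ± 0.0585) and Sparc (29.0 ± 13.3 CPM against 0.471 ± 0.438) were among them, and Lum rose by at least 469-fold. Large rises included genes of neutrophils and their precursors: Ngp (at least 5084-fold), Camp (at least 3297-fold), Chil3 (at least 1861-fold), Elane (at least 707-fold), Ly6c2 (at least 675-fold) and S100a8, with 6802 counts against 1 (ratio 31022, 5566 to 1225470). Without knockout replicate 1 the bounds were 3303 for Ngp, 801 for Chil3 and 367 for Ly6c2, and without replicate 2 that of Lum was 296. Of 18 immune cell genes 4 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.514), and 1 of 5 endothelial genes rose (none adjusted over the list alone; 0.535). Large falls included the transcription factor Osr2 (-6.47, 0.000422), Nr2e3 (-6.46, 0.00910), Spns2 (-5.61, 0.00871), Trpm5 and Angpt2 (3 counts against 1021, wild type higher by a ratio of 74.6, 25.5 to 362). Of these, Nr2e3 and Spns2 lost the call without at least 1 library. With n = 2 and genotype tied to another reporter and Cre allele and to tamoxifen, the comparison does not separate Ascl2 loss from those alleles or that treatment. Which cells in the knockout sort carried the stromal and neutrophil transcripts was not tested.

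**Figure D1:**
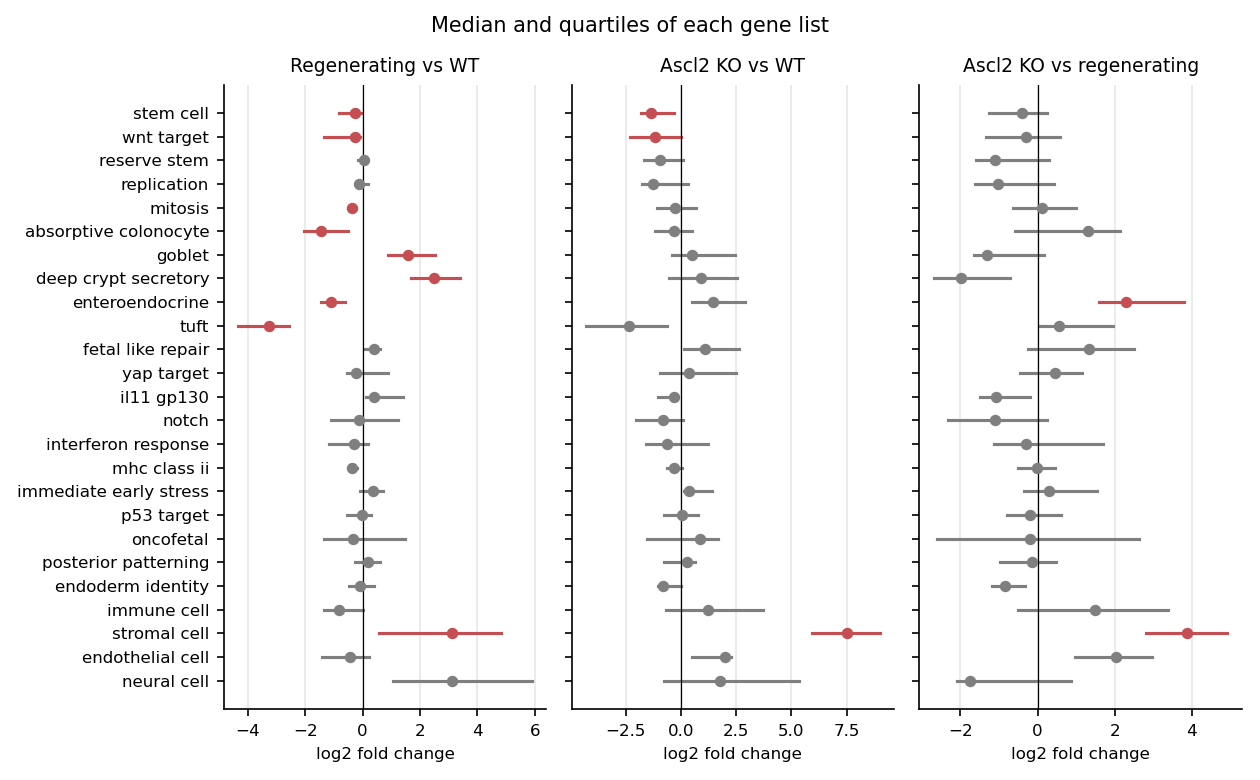
Median (point) and quartiles (line) of the fitted log2 fold change of each of the 25 lists in the 3 adult comparisons; red marks lists that passed the list test, grey those that did not. In regenerating against wild-type cells the goblet, deep crypt secretory and stromal lists lie above 0 and the tuft list lies below; in knockout against wild-type cells the medians of deep crypt secretory, goblet, immediate-early, oncofetal, p53, posterior patterning and YAP lists flip by library size scaling.

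The comparison of Ascl2-deleted with regenerating cells is also the test of whether the 2 departures from wild type differ. Spdef, which had risen in regenerating cells, and Atoh1, which had not passed there (adjusted p = 0.0809), were lower in the knockout cells: Spdef stood at 48.4 ± 0.247 CPM against 430.0 ± 219.8 and Atoh1, the transcription factor that sets secretory fate, at 48.2 ± 1.15 CPM against 221 ± 12.03. Hes1, a Notch effector that represses Atoh1, stood at 655 ± 73.1 CPM against 154 ± 32.3. Pyy stood at 1639 ± 262 CPM against 12.1 ± 11.2. Il11ra1 stood at 7.67 ± 4.31 CPM against 31.6 ± 3.76.

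edgeR called 4362 of 13911 genes (31.4%), 2139 up and 2223 down in the knockout, and 3938 changed at least 2-fold. By library size 5478 were called, 1070 up and 4408 down, with the median of all genes shifted by -0.80; it shifted by 0.11 with upper-quartile factors and by 0.17 with offsets for span. Without regenerating replicate 2, 2446 genes were called, without regenerating replicate 1, 2729, and without knockout replicate 1, 2905. Spdef had a log2 fold change -3.15 ± 0.41 (SE), adjusted p = 0.000682. Atoh1 (chromosome 6, 64729125 to 64731245) had a log2 fold change -2.20 ± 0.38 (SE), adjusted p = 0.00281, and Hes1 (chromosome 16, 30065357 to 30067796) a log2 fold change 2.09 ± 0.27 (SE), adjusted p = 0.000663. Pyy had a log2 fold change 7.08 ± 0.72 (SE), adjusted p = 0.000259. Ascl2 (log2 fold change -0.34, adjusted p = 0.414, 0.0115 to 0.973 over 16 alternatives) and Lgr5 (0.64, 0.524, 0.111 to 0.970 over 16 alternatives; -0.14 by library size) did not pass; Ascl2 passed by library size (0.0162) and with offsets for span (0.0115). Il11ra1 fell (log2 fold change -2.04 ± 0.62 (SE), adjusted p = 0.0346, 0.00519 to 0.175 over 16 alternatives) but lost the call without wild-type replicate 3 (0.0521), regenerating replicate 1 (0.0919) or 2 (0.132), or knockout replicate 1 (0.175). Ly6a had a log2 fold change of 2.51 (adjusted p = 0.0810, 0.00602 to 0.439 over 16 alternatives). Of 81 calls followed singly, 46 kept the call whichever library was left out and 35 did not. In the next paragraph lost calls are marked for the large falls only.

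Of 20 goblet genes 7 fell and 2 rose (7 and 3 adjusted over the list alone). The goblet list had a median log2 fold change of -1.31 (adjusted p = 0.105), with adjusted p = 0.891 with an estimated correlation. Of 7 deep crypt secretory genes 4 fell and 1 rose (the same adjusted over the list alone). The deep crypt secretory list had a median log2 fold change of -1.995 (adjusted p = 0.105), with adjusted p = 0.891 with an estimated correlation. Reg4 (-2.38, 0.00687), the growth factor activator Hgfac (-3.17, 0.000533) and the receptor Kit (-2.98, 0.00255) were among the falls. Of 21 enteroendocrine genes 5 rose (5 adjusted over the list alone). The enteroendocrine list had a median log2 fold change of 2.30 (adjusted p = 0.00856), with adjusted p = 0.891 with an estimated correlation. Insl5 (5.95, 0.00133) and glucagon, Gcg (5.27, 0.00704), were 2 of the rises. Of 13 stromal genes 6 rose (9 adjusted over the list alone). The stromal list had a median log2 fold change of 3.87 (adjusted p = 0.0192), with adjusted p = 0.891 with an estimated correlation. Of 20 stem cell genes 7 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.151), with Ephb3 at -2.42 (0.000271). Cdkn1a (3.51, 0.00170), S100a6 (3.28, 0.000406) and Areg (3.18, 0.00310) rose. Large rises included Camp (at least 2123-fold), Ngp (ratio 3281, 1122 to 15916), S100a8 (309 ± 93.1 CPM against 0.0748 ± 0.106), Elane (at least 455-fold), Fabp1 (at least 429.7-fold) and Hp (at least 320.3-fold). The bound of Fabp1 was 274 without knockout replicate 2 and that of Hp 181 without replicate 1. Large falls included Ido1 (-7.58, 0.0232), Spns2 (-5.77, 0.00999), Gfi1 (-5.08, 0.0122), Fzd9 (-5.08, 0.00943), Piwil4 (-4.90, 0.00585) and Dlk1 (-4.77, 0.00451), of which Ido1, Spns2, Gfi1 and Fzd9 lost the call without at least 1 library.

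The hindgut libraries ask how the epithelium matures between E11 and E16. Genes of differentiated epithelium rose steeply: Tff3 stood at 2401 ± 461 CPM against 7.53 ± 0.233, guanylin, Guca2a, at 634 ± 75.4 CPM against 0.114 ± 0.161 and the brush border protein villin, Vil1, at 247 ± 1.55 CPM against 16.5 ± 0.931. Atoh1 was at 0 in both E11 libraries and at 184 and 155 CPM at E16. Genes of the early embryonic programme fell, with the RNA-binding protein Lin28b at 1.01 ± 0.577 CPM against 40.1 ± 7.12 and the chromatin protein Hmga2 at 47.2 ± 17.7 CPM against 509 ± 111. Transcripts of other tissues rose at E16 as well, such as the macrophage lysozyme Lyz2 (at least 16277-fold) and smooth muscle myosin, Myh11 (at least 7076-fold). At E16 3.09 and 3.50% of reads were ambiguous between genes, against 0.7995 to 1.10% in the 13 other libraries.

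Of 16481 genes tested, 9188 (55.7%) differed between E16 and E11, 4873 up and 4315 down, and 10388 (63.0%) changed over the 4 ages (edgeR F test). Without the E16 libraries, an alternative chosen after the data had been seen, 5483 changed over the remaining ages and 6196 differed between E14 and E11. Ascl2 rose (5.95 ± 0.121 CPM against 2.14 ± 0.641; log2 fold change 1.47 ± 0.49 (SE), adjusted p = 0.0354, 0.00238 to 0.120 over 15 alternatives), and so did Il11ra1 (21.99 ± 2.90 CPM against 10.9 ± 3.64; log2 fold change 1.01 ± 0.33 (SE), adjusted p = 0.0316, 0.0103 to 0.180 over 15 alternatives). Ascl2 lost the call without E11 replicate 1 (0.0882), E14 replicate 1 (0.0659) or 2 (0.0688), or E16 replicate 1 (0.120) or 2 (0.109), and Il11ra1 without E11 replicate 2 (0.0955), E14 replicate 1 (0.0543) or 2 (0.0546), or E16 replicate 1 (0.149) or 2 (0.0717). Il11ra1 was at 6.62 and 7.01 CPM at E14, so its rise lay between E14 and E16. Transcripts of other tissues rose there as well, and which cells carried the Il11ra1 rise was not tested. Lgr5 (13.6 ± 5.75 CPM against 10.9 ± 6.59, adjusted p = 0.612, 0.0876 to 0.865 over 15 alternatives) and Ly6a (11.7 ± 0.311 CPM against 9.96 ± 5.95, 0.640, 0.0265 to 0.876 over 15 alternatives) did not pass. Besides Lyz2 and Myh11, large rises included Cdh17, an intestinal cadherin (at least 8662-fold), F13a1 (at least 5882-fold), Ern2 (at least 5053-fold) and Klk1 (at least 4551-fold). Large falls included Emx2 (at least 868.2-fold lower), Cdh16 (407-fold), Dppa3 (339-fold), Dppa5a (296-fold), Emx2os (283-fold) and Trp63 (213-fold), each a lower bound. With 1 E11 library left out, these bounds moved most: Cdh16 (142 without replicate 1), and Dppa3 (224), Dppa5a (189.7) and Trp63 (36.97) without replicate 2. The floor was kept at both E16 libraries, so bounds without an E16 library were not computed. Trp63 was at 3.76 and 39.5 CPM in the E11 libraries and higher at E14 (90.6 and 144 CPM). Dppa5a (0.0503) and Emx2os (0.0535) lost the call without E16 replicate 1. Library size, upper-quartile or DESeq2 scaling each shifted the median of all genes by less than 0.1 in the hindgut comparisons.

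Of the 25 lists, 14 passed; counts adjusted over the list alone were the same unless given. All 20 goblet genes rose (20 adjusted over the list alone). The goblet list had a median log2 fold change of 8.31 (adjusted p = 7.44e-28), with adjusted p = 0.00633 with an estimated correlation and 3.22e-28 to 0.0392 over 13 alternatives. Agr2 had a log2 fold change of 10.30 (1.03e-05) and Spdef of 5.78 (6.47e-06). Of 25 absorptive colonocyte genes 18 rose and 4 fell. The colonocyte list had a median log2 fold change of 4.67 (adjusted p = 2.16e-10), with adjusted p = 0.0224 with an estimated correlation and 1.07e-10 to 0.0224 over 13 alternatives. The adhesion molecule Ceacam1 was at 8.61 (1.01e-06). Of 19 fetal-like repair genes 14 rose and 3 fell. The fetal-like repair list had a median log2 fold change of 2.15 (adjusted p = 1.61e-05), with adjusted p = 0.0448 with an estimated correlation and 9.53e-09 to 0.0448 over 13 alternatives. All 16 immediate-early genes rose. The immediate-early list had a median log2 fold change of 5.89 (adjusted p = 1.03e-21), with adjusted p = 0.0312 with an estimated correlation and 8.48e-22 to 0.0312 over 13 alternatives. Of 14 oncofetal genes 11 fell. The oncofetal list had a median log2 fold change of -1.39 (adjusted p = 1.61e-05), with adjusted p = 0.0448 with an estimated correlation and 8.88e-06 to 0.0448 over 13 alternatives. The falls included Lin28b (-5.28, 4.66e-05), Hmga2 (-3.44, 3.53e-05) and Igf2bp1 (-2.14, 6.26e-06). Of 26 mitosis genes 20 fell and 1 rose (21 and 1 adjusted over the list alone). The mitosis list had a median log2 fold change of -0.74 (adjusted p = 2.10e-06), with adjusted p = 0.123 with an estimated correlation and 4.17e-08 to 0.151 over 13 alternatives. Of 24 replication genes 16 fell and 1 rose. The replication list had a median log2 fold change of -0.75 (adjusted p = 0.000282), with adjusted p = 0.315 with an estimated correlation and 4.31e-07 to 0.940 over 13 alternatives. Of 10 interleukin 11 and gp130 genes 9 rose. The gp130 list had a median log2 fold change of 1.76 (adjusted p = 0.00382), with adjusted p = 0.142 with an estimated correlation and 0.000181 to 0.142 over 13 alternatives. Stat3 was at 3.66 (1.69e-05) and its feedback inhibitor Socs3 at 5.60 (0.000160). Of 12 tuft genes 10 rose (11 adjusted over the list alone). The tuft list had a median log2 fold change of 4.79 (adjusted p = 0.00210), with adjusted p = 0.152 with an estimated correlation and 0.000283 to 0.442 over 13 alternatives. Of 14 Notch genes 6 rose and 1 fell (0.0798 without E16 replicate 1). The Notch list had a median log2 fold change of 1.29 (adjusted p = 0.0207), with adjusted p = 0.204 with an estimated correlation and 0.00132 to 0.204 over 13 alternatives.

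Stem cell genes went both ways (9 up, 5 down of 22, adjusted p = 0.338), as did Wnt targets (5 up, 6 down of 19, 0.508) and YAP targets (9 up, 6 down of 21, 0.508). So did p53 targets (6 up, 2 down of 15, 0.512), endoderm identity genes (7 up, 5 down of 14, 0.316) and reserve stem cell genes (2 up, 2 down of 6, 0.493; median -0.44 but mean 1.16). Deep crypt secretory genes (5 up, 1 down of 7, 0.0675), enteroendocrine genes (15 up, 3 down of 22, 16 and 3 adjusted over the list alone, 0.0675) and posterior patterning genes (3 up, 10 down of 18, 0.0549) missed the threshold. With 1 library left out, deep crypt genes passed except without E16 replicate 2 (0.00440 to 0.0478), enteroendocrine genes passed in all 8 cases (0.00159 to 0.0422), and posterior patterning genes passed except without E11 replicate 2 (0.0113 to 0.0339). From E11 to E14, without the E16 libraries, replication (0.940) and mitosis genes (0.151) had no fall, and the enteroendocrine list lay lower (0.0151).

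Immune and stromal genes, markers of cells that the Epcam sort selects against, rose at E16. Of 20 immune cell genes 18 rose (19 adjusted over the list alone). The immune list had a median log2 fold change of 10.80 (adjusted p = 1.85e-10), with adjusted p = 0.147 with an estimated correlation and 2.64e-15 to 0.147 over 13 alternatives. The median was 8.23 with 13 all-0 genes at their bound, and the macrophage receptor Csf1r stood at 257 ± 17.8 CPM against 0.169 ± 0.239. Of 14 stromal genes 10 rose and 2 fell (11 and 2 adjusted over the list alone). The stromal list had a median log2 fold change of 6.88 (adjusted p = 0.00109), with adjusted p = 0.217 with an estimated correlation and 6.95e-05 to 0.586 over 13 alternatives. The matrix gene Col6a1 stood at 586 ± 117 CPM against 1.39 ± 1.16 and Dcn at 443 ± 30.2 CPM against 3.08 ± 0.909. Of 8 MHC class II genes, which sorted adult epithelium carries too (Cd74 at 142 to 6265 CPM in wild-type stem cells), 7 rose. The MHC class II list had a median log2 fold change of 4.26 (adjusted p = 0.00210), with adjusted p = 0.111 with an estimated correlation and 0.000181 to 0.294 over 13 alternatives. The invariant chain Cd74 stood at 460.4 ± 0.965 CPM against 0.471 ± 0.666. Of 21 interferon response genes 12 rose and 1 fell. The interferon list had a median log2 fold change of 3.43 (adjusted p = 0.0298), with adjusted p = 0.147 with an estimated correlation and 3.85e-05 to 0.340 over 13 alternatives. Endothelial (5 up of 8, adjusted p = 0.209; 0.0448 and 0.0230 without E12 replicate 1 and 2) and neural genes (4 up, 2 down of 9, 4 and 3 adjusted over the list alone, 0.915) did not pass. Adult haemoglobin genes of the red cell list had no counts in nearly all libraries, but Alas2, the erythroid enzyme of haem synthesis, stood at 1483 ± 58.7 CPM against 0.811 ± 0.828. Reads that align to several places or are ambiguous between genes enter no gene count. The missing haemoglobin counts therefore do not show that adult haemoglobin RNA was absent. Embryonic globins were present at E11 already: Hbb-y was at 220.6 and 98.7 CPM at E11 and at 30.4 and 44.4 at E16, and Hba-x at 88.0 and 37.2 and at 41.3 and 53.3 CPM.

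**Figure D2:**
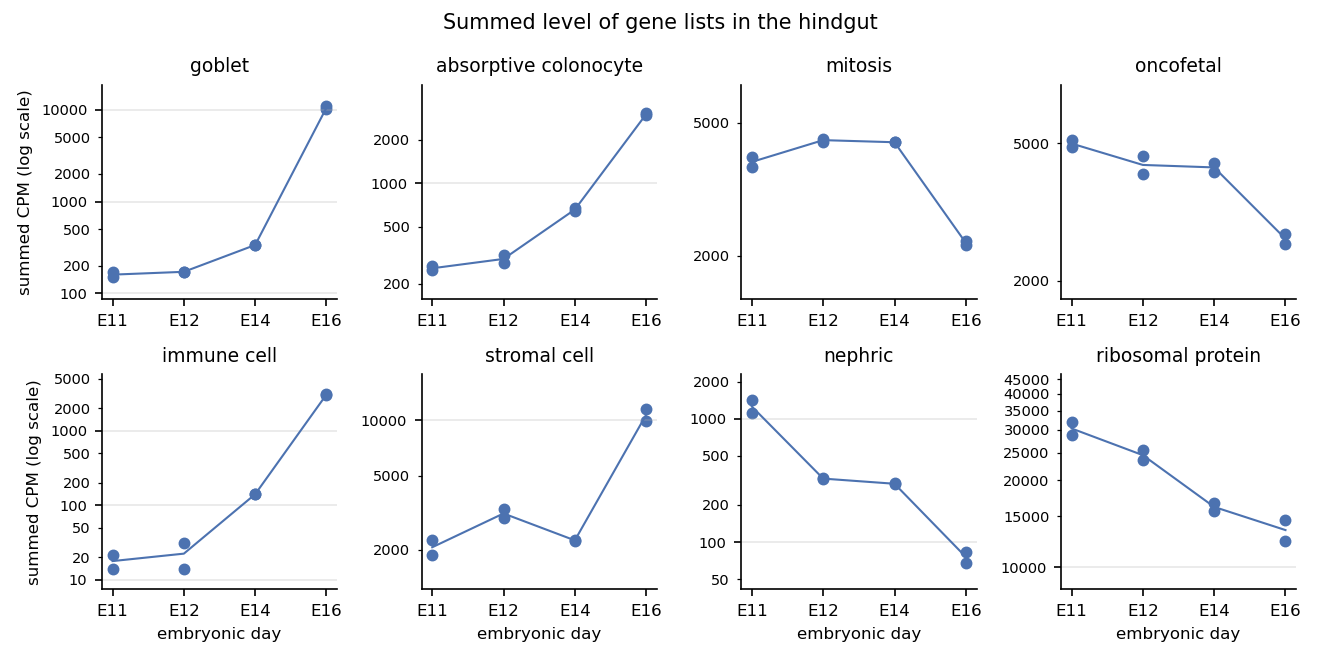
Summed CPM on a log axis of goblet, absorptive colonocyte, mitosis, oncofetal, immune cell, stromal cell, nephric and ribosomal protein genes in each hindgut library (points) by embryonic age, with the mean as a line. Goblet genes sum to 159.8 ± 14.5 CPM at E11 and 10537 ± 465 at E16, and immune cell genes to 17.8 ± 5.36 and 3075 ± 66.2. The nephric sum at E14 is mostly Wfdc2.

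Between neighbouring ages, 434 genes differed from E11 to E12 (290 up, 144 down), 4672 from E12 to E14 (2381 up, 2291 down) and 6530 from E14 to E16 (3394 up, 3136 down). Both E14 libraries stood apart in Lars2 and Malat1, picked after their values were seen. Lars2 was at 4080 and 3460 CPM there against 319 to 910 at the other ages, and Malat1 at 554 and 401 against 2579 to 3913. Library making at E14 was thus not separated from age in the steps into and out of E14. At the first step Cdh17 (at least 288-fold), the epithelial factor Klf5 (2.03, adjusted p = 0.000804) and Clrn3 (ratio 102, 34.5 to 496) rose, and Gata3 (-2.30, 0.000804) and Id4 (-2.60, 0.00143) fell. At the second, Ckmt1 (4.49, 3.07e-05), Cdh17 (4.00, 3.07e-05) and Ceacam1 (4.78, 3.22e-05) rose, while the neuronal genes Map1b (-3.22, 3.07e-05) and Uchl1 (-3.16, 3.07e-05) and Zcchc18 (-2.79, 4.65e-05) fell. At the last, Apoe (3.75, 3.46e-06), Fech (3.38, 3.46e-06) and Tff3 (7.54, 3.46e-06) rose, and Cldn6 (-4.14, 1.80e-06), Sall4 (-7.15, 4.42e-06) and Cdh3 (-3.30, 1.02e-05) fell. Ly6a went up and then down, at 9.96 ± 5.95, 25.3 ± 7.13, 50.4 ± 4.04 and 11.7 ± 0.311 CPM over the 4 ages, and its last step passed (-2.10, 0.00605, 1.57e-05 to 0.122 over 15 alternatives). So did that of Il11ra1 (1.69, 0.00625, 3.68e-05 to 0.0578 over 15 alternatives; 0.0542 without E14 replicate 1). All 26 mitosis genes fell from E14 to E16 (26 adjusted over the list alone; median -0.99, adjusted p = 2.17e-15, adjusted p = 0.0379 with an estimated correlation). The first step gave 704 and 919 calls without E11 replicate 1 and 2, 278 and 217 without E12 replicate 1 and 2, 119 and 122 without E14 replicate 1 and 2, and 154 and 135 without E16 replicate 1 and 2; DESeq2 gave 1493 (860 up, 633 down). The second gave 1717 and 1877 without E14 replicate 1 and 2 and 3104 without E12 replicate 1. The last gave 3468 and 3569 without E14 replicate 1 and 2, and 3919 and 3979 without E16 replicate 1 and 2.

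Testing hindgut genes in the adult cells asks whether regenerating or Ascl2-deleted cells carry an embryonic programme. The 200 genes most clearly higher at E11, and the 200 higher at E16, came from libraries that enter no adult comparison. In regenerating cells the E11-high set lay below wild type (1 of 200 fell and none rose, 2 and 2 adjusted over the list alone; median -0.10, adjusted p = 0.00592, adjusted p = 0.446 with an estimated correlation). The E16-high set lay above it (8 rose and none fell, 26 and 7 adjusted over the list alone; median 0.15, adjusted p = 0.000225, adjusted p = 0.446 with an estimated correlation). The goblet list lay higher in regenerating cells and at E16 too. Whether goblet genes account for the rise of the E16-high set was not tested. In Ascl2-deleted cells the E11-high set was higher than in wild type (76 rose and 20 fell, 82 and 22 adjusted over the list alone; median 0.63, adjusted p = 0.000225, adjusted p = 0.446 with an estimated correlation). The E16-high set did not pass (41 rose and 56 fell, 44 and 60 adjusted over the list alone; median -0.25 but mean 0.25, adjusted p = 0.284, adjusted p = 0.709 with an estimated correlation). Against regenerating cells, the E11-high set was higher in the knockout (71 rose and 12 fell, 76 and 14 adjusted over the list alone; median 0.78, adjusted p = 3.05e-06, adjusted p = 0.446 with an estimated correlation). The E16-high set was lower (32 rose and 62 fell, 35 and 69 adjusted over the list alone; median -0.48, adjusted p = 0.0131, adjusted p = 0.499 with an estimated correlation). Of the E11-high genes 8 encode ribosomal proteins, which rose in the knockout; with these left out, chosen after the data had been seen, E11-high genes were still higher in the knockout (adjusted p = 0.000410 against wild type and 7.64e-06 against regenerating cells). At least 51.2% of knockout reads aligned to several places, so library quality is not separated from genotype here either. Without regenerating replicate 2, the regenerating tests gave 0.662 for E11-high and 0.159 for E16-high genes, and the knockout against regenerating test of E16-high genes gave 0.0574. With sets from E14 against E11, chosen after the data had been seen, the regenerating tests gave 0.841 for E11-high genes and, now downward, 0.0901 for late-high genes, and the knockout against wild-type test of late-high genes passed downward (0.00844).

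The day 8 single-cell library asks which cells make up the regenerating population. It held 3251 cells in 13 clusters, at a median of 21590 UMIs and 4525 genes per cell. Cells with cell cycle markers made up 52.3% (1699 cells; 95% Clopper-Pearson interval 50.5 to 54.0%), cells with secretory markers 23.3% (756; 21.8 to 24.7%), colonocyte-like cells 7.51% (244; 6.62 to 8.47%), and 17.0% (552; 15.7 to 18.3%) met no class. Of the cycling-like cells, 508 and 222 lay in 2 clusters with medians of only 40.5 and 44 UMIs of cell cycle markers per cell, near the 42 of an unnamed cluster and below the 110.5 to 181 of the other cycling-like clusters. Mki67 was at 78.7 and 95.9 CPM there, below the 110.4 of 1 colonocyte-like cluster. By class, Ascl2 was highest in cycling-like cells and Il11ra1 in secretory-like cells. By cluster, Ascl2 peaked at 32.1 CPM in the cycling-like cluster of 508 cells, where Mki67 was at 78.7. It was at 20.6 and 17.8 CPM in the cycling-like clusters with the most Mki67 (512 and 470). The remaining cycling-like clusters held 24.3 and 24.7 CPM of Ascl2, and an unnamed cluster 17.1. The shares moved with the settings: the cycling-like share ran from 37.0% with doublets kept to 65.3% with no mitochondrial limit. These settings held 3253 and 3262 cells against 3251. The shift thus lay mostly in cells that were clustered and named otherwise, not in added cells. The secretory-like share ran from 9.56% with droplets called at a higher UMI threshold to 29.0% without clusters of mixed content.

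Ascl2 reached 23.8 (22.5 to 25.3) CPM of summed UMIs (95% Poisson interval) in cycling-like cells, 6.35 (4.87 to 8.14) in secretory-like and 2.29 (1.25 to 3.85) in colonocyte-like cells, with 15.3 in empty droplets. A UMI was present in 40.8% of cycling-like cells (median depth 26065 UMIs) and in 4.10% of colonocyte-like cells, which should lack it (19653 UMIs), or 12.7 and 1.23% with cells thinned to 6000 UMIs. Lgr5 was near the background, at 2.79 (2.34 to 3.31) CPM in cycling-like cells and 1.80 in empty droplets. The toxin had killed Lgr5-positive cells and the sort took GFP-negative cells, so the design itself favoured a low Lgr5 level. Il11ra1 reached 44.9 (40.8 to 49.3) in secretory-like, 11.2 (10.3 to 12.2) in cycling-like and 6.72 (4.82 to 9.11) in colonocyte-like cells; 43.4% of secretory-like cells had a UMI (median depth 12615) and 14.8% of colonocyte-like cells, or 23.8 and 3.69% when thinned. Ly6a was highest in colonocyte-like cells (2309), with 307 in cycling-like and 147 in secretory-like cells and 468 in empty droplets. Summed mitosis genes came to 2536 CPM in cycling-like, 104 in secretory-like and 565 in colonocyte-like cells. Cells of 1 library are not replicates.

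**Figure D3:**
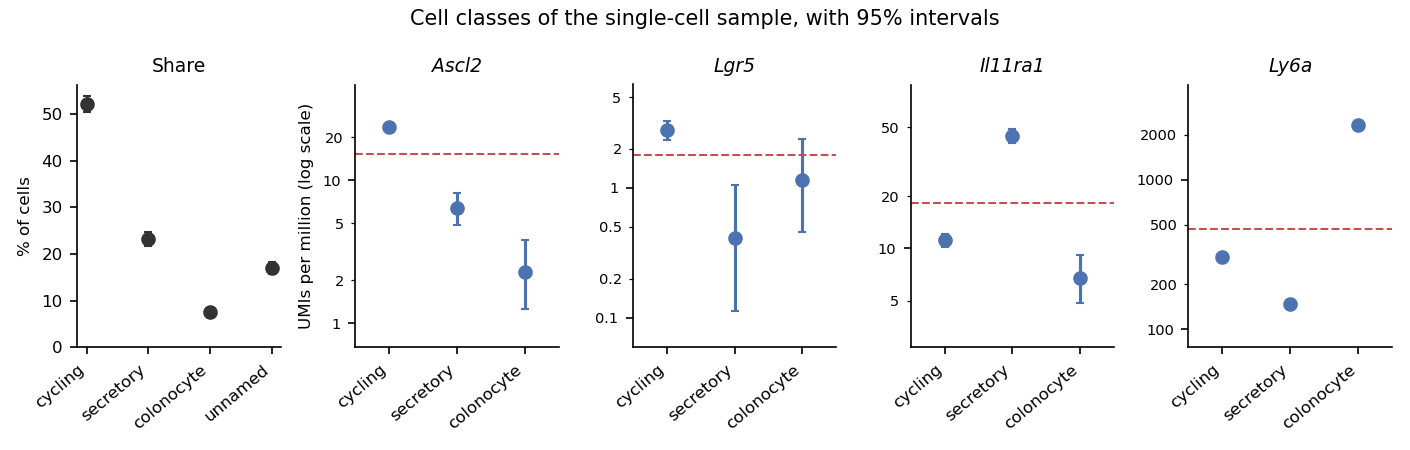
Share of cells per class with 95% Clopper-Pearson intervals, and CPM of Ascl2, Lgr5, Il11ra1 and Ly6a by class with 95% Poisson intervals; dashed red lines mark empty droplets. Ascl2 is highest in cycling-like, Il11ra1 in secretory-like and Ly6a in colonocyte-like cells.

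The secretory class carried the genes that rose in bulk. Reg4 reached 10449 CPM there against 44.2 in cycling-like cells outside 3 clusters of mixed content, Spink4 34969 against 81.2, and Atoh1 282 against 2.47. Of 39 genes that rose in regenerating bulk libraries and were detected, 38 were highest in secretory-like cells, where 10000 random lists of like expression gave a median of 11 and at most 22; the exception was Cxcl2, highest in cycling-like cells. With class markers left out it was 33 of 34. Of the 4 genes that fell in bulk, Smoc2 and Sox4 were detected and both were highest in cycling-like cells outside the mixed clusters, at 45.9 and 112 CPM, as in 1942 of 10000 random lists. The 392 detected genes that were lower in bulk at an unadjusted p below 0.05 went to another class: 210 were highest in colonocyte-like cells (random median 107, at most 142) and 153 in cycling-like cells (random median 168). The 3 mixed clusters held 642 cells (19.7%, 18.4 to 21.2%) that were not secretory-like but carried 17455 to 37409 CPM of secretory markers, against 764 to 1863 in the other clusters outside the secretory class.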

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

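The tests in this part, library size scaling and the offsets for genomic span were chosen after the results had been seen.

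Reads that no gene count uses differed between groups. Reads without a feature made up 6.90 and 8.94% in the regenerating and 7.71 and 9.77% in the knockout libraries, above the 5.77 to 6.68% of wild type. Reads aligned to several places made up 51.2 and 51.4% in the knockout libraries, above the 39.1 to 40.2% of wild type. Ambiguous reads made up 3.09 and 3.50% at E16, above the 0.858 to 0.866% of E11.

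The knockout libraries differed from wild type in 5039 genes. A trend of counts with genomic span as the whole cause is argued against, since 80.8% of these calls (4070) remained in the same direction with each library's trend removed. Fewer epithelial cells in the knockout sort is argued against as the whole cause of the falls, since Epcam, Cdh1, Krt8, Krt18 and Krt19 had a median log2 fold change of 0.38 (-1.14 to 0.98) where the 2421 falls had a median of -1.51, and by library size -0.60 (-2.12 to -0.0044) against -2.01. By library size Cdh1 fell as far as the median fall. On the TMM scale 7 of 12 endoderm identity genes fell, so a share of the falls stays open to it. RNA quality or library making stays open, since at least 51.2% of knockout reads aligned to several places against 36.4 to 40.2% in the other adult libraries, and Malat1 and Lars2, picked after their values were seen, were at 17182 and 10270.1 CPM against 2322 and 322 in wild type. It cannot be told apart from genotype because every knockout library shares it. Loss of Ascl2 stays open as well, untested against the Cre and reporter alleles and the tamoxifen that come with it.

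Transcripts of stromal, immune, endothelial and neural cells rose together from E14 to E16, although the sort on Epcam would remove such cells. Cells of other types among the sorted cells are a candidate source: the 4 lists, which share no gene with another list, rose by medians of 5.45, 5.89, 4.03 and 3.29 on the log2 scale, and Col6a1 and Csf1r reached 586 and 257 CPM at E16 against 4.18 and 20.9 at E14. Other counting rules at E16 are argued against, since the 37 list members that overlap no other gene rose by a median of 5.15 (quartiles 3.46 to 6.81). Of the 20 immune genes, 13 had no counts in 1 of the groups E11 and E16. A change of the epithelium with age stays open and was not tested; Epcam itself was at 1411 ± 25.01 CPM at E14 and 1225 ± 68.7 at E16.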

How the results depend on the processing

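The alternatives by library size, with offsets for genomic span, without the E16 libraries, without ribosomal protein, oxidative phosphorylation and histone genes in the hindgut sets, and without mixed clusters were chosen after the data had been seen. The counts of genes for knockout against wild type (4353 to 6930) and against regenerating cells (3563 to 5784) stayed within 1.5 times the reported count under all 9 settings other than leaving out a library. With n = 2 per group in all groups but wild type, simulated 2-fold changes were recovered for 2 to 4 of 100 genes in the adult fits, so absence from the calls says little there. Leaving a group with 1 library assumes that it varies like the other groups. Where a count moved or a direction turned below, the cause was not tested, except that fewer libraries or genes entered the fit where libraries were left out. Over all alternatives, named genes kept their side of the threshold in 5600 cases (18 of them with a change of sign in an uncalled gene), gained the call in 109, lost it in 378 and turned, with a call on either side, in 7. For lists it was 806 (57 with a change of sign), 76, 38 and 5. The replicate number as a block was tried because equal numbers could mark a shared day, yet residuals of equal numbers correlated by only 0.00964 to 0.107 in the adult and -0.0295 to 0.0425 in the hindgut libraries.

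Regenerating against wild type gave 225 calls without a filter, 6 with only the 2 groups compared, 635 with all 15 libraries in 1 fit and 470 with DESeq2. All 15 libraries in 1 fit gave 5970 for E16 against E11, 107 for E12 against E11, 1542 for E14 against E12, 2773 for E16 against E14 and 6334 over all ages, and 5483 changed over the ages without the E16 libraries. E12 against E11 gave 266 with the block, 54 with only the 2 groups compared and 1493 with DESeq2. With an estimated correlation 1 list passed in regenerating cells, 0 in the knockout and 5 in the hindgut; with fry 3, 7 and 23. In the knockout 5 lists passed with the block and 7 by library size.

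With 1 library left out, the counts ranged from 1 to 39 for regenerating against wild type, 3413 to 4577 for knockout against wild type, 2446 to 4668 for knockout against regenerating, 6385 to 9209 for E16 against E11, 119 to 919 for E12 against E11, 1717 to 5846 for E14 against E12, 3468 to 7888 for E16 against E14 and 7767 to 11333 over all ages. Lists passing ranged from 8 to 12 in regenerating cells, 1 to 7 in the knockout and 16 to 18 in the hindgut. The adjusted p ranged from 3.73e-07 to 0.662 for E11-high and 3.09e-06 to 0.159 for E16-high genes in regenerating cells, from 0.000253 to 0.00358 and 0.129 to 0.873 in the knockout against wild type, and from 1.78e-07 to 0.000265 and 0.00142 to 0.0574 against regenerating cells.

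With an estimated correlation, the E11-high set gave an adjusted p of 0.446 in all 3 adult comparisons, and the E16-high set 0.446 in regenerating cells and 0.499 in knockout against regenerating cells. Sets from E14 against E11 gave 0.841 for early genes in regenerating cells, 0.0901 with a turned direction for late genes, and 0.00844 for late genes in the knockout against wild type. The top 100 E16-high genes gave 0.0764 in knockout against regenerating cells.

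Directions turned in the knockout against wild type for Mki67 (-0.046), Anxa2 (-0.038), Hes1 (-0.014), Hoxb13 (-0.17) and Krt19 (-0.0044) by library size, and for Hes1 (-0.26) and Hoxb13 (-0.49) with offsets for span. From E11 to E14 the lists for replication (0.940) and mitosis (0.151) turned up, and those for enteroendocrine (0.0151), MHC class II (0.294) and neural cells (0.0148) turned down.

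The cycling-like, secretory-like and colonocyte-like shares were 63.0, 9.56 and 10.9% with droplets called at the higher UMI threshold. With at most 10% mitochondrial UMIs the cycling-like, colonocyte-like and unnamed shares were 43.2, 9.13 and 24.3%. With no mitochondrial limit the cycling-like share was 65.3% and the unnamed 3.95%, and with doublets kept 37.0 and 32.3%. The cell numbers were then 3262 and 3253 against 3251, so these moves lay mostly in cells named otherwise. The cycling-like, colonocyte-like and unnamed shares were 37.3, 11.2 and 28.3% at resolution 0.4 and 49.8, 6.12 and 20.8% at 1.2. Without mixed clusters the shares were 56.3% cycling-like, 29.0% secretory-like, 9.35% colonocyte-like and 5.40% unnamed.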

Other observations

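Of the tests in this part, that of 2 cells in 1 droplet was set before its result was seen; the free RNA test and the 8 added gene lists were chosen after.

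Beyond the fixed lists, the knockout libraries differed from wild type in genes of basic cell machinery and of granulocytes. Which cells in the knockout sort carried the granulocyte transcripts was not tested. Of 11 neutrophil genes 10 rose (11 adjusted over the list alone; median log2 fold change 10.79, or 8.11 at the bounds, adjusted p = 4.61e-13, adjusted p = 0.0636 with an estimated correlation), to a summed 952 ± 372 CPM against 8.28 ± 10.8. Of 76 ribosomal protein genes 63 rose and none fell (66 adjusted over the list alone; median 2.08, adjusted p = 3.72e-27, adjusted p = 0.144 with an estimated correlation); by library size 43 rose and 1 fell. Of 75 oxidative phosphorylation genes 62 rose and 4 fell (64 and 4 adjusted over the list alone; median 2.70, adjusted p = 2.34e-41, adjusted p = 0.144 with an estimated correlation). Of 48 histone genes 23 rose and 1 fell (26 and 1 adjusted over the list alone; median 2.70, adjusted p = 3.27e-07, adjusted p = 0.144 with an estimated correlation). Of 8 chaperonin genes, which fold newly made proteins, 7 fell (7 adjusted over the list alone; median -1.17, adjusted p = 0.00181, adjusted p = 0.388 with an estimated correlation). In the same knockout libraries 3 further genes, picked after their values were seen, were high: Lars2 at 10270.1 ± 3496 CPM against 322 ± 232, the nuclear RNA Malat1 at 17182 ± 5260 against 2322 ± 877, and the ribosomal RNA precursor Rn45s at 8951 ± 2129 against 1757 ± 742. RNA quality or library making was not separated from genotype for any of these. None of the 5 lists above had a called gene in regenerating against wild-type cells (adjusted p from 0.462 to 0.561). Germ cell (0.649), nephric (0.175) and basal squamous genes (0.691, median 0.09 but -0.88 by library size and -0.55 with offsets for span) did not pass in the knockout.

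In the hindgut, the nephric list lay lower at each step up to E14. From E11 to E12, 3 of 9 genes fell (6 down and 1 up adjusted over the list alone). The camera adjusted p was 1.02e-09, or 0.209 with an estimated correlation. From E12 to E14, 6 fell (7 adjusted over the list alone), at a camera adjusted p of 6.51e-05, or 0.352 with an estimated correlation. Of 9 nephric genes 8 fell from E11 to E16 (8 adjusted over the list alone; median -7.67, or -6.99 at the bounds, adjusted p = 6.95e-08, adjusted p = 0.154 with an estimated correlation), from a summed 1254 ± 212 CPM through 327 ± 6.65 and 297 ± 4.67 to 75.9 ± 11.4. The last step was a drop in the sum only, with 2 genes up and 2 down (the same adjusted over the list alone; adjusted p = 0.806, adjusted p = 0.892 with an estimated correlation). Of 12 germ cell genes 7 fell and 1 rose (8 and 2 adjusted over the list alone; adjusted p = 0.216). Basal squamous genes were highest at E14, at 1468 ± 245 CPM against 66.9 ± 3.26 at E12 and 204 ± 9.90 at E16: 6 of 8 rose from E12 to E14 (7 adjusted over the list alone; adjusted p = 6.51e-05, adjusted p = 0.352 with an estimated correlation) and 5 fell to E16 (5 adjusted over the list alone; adjusted p = 0.00360, adjusted p = 0.782 with an estimated correlation). Library making at E14, where Lars2 and Malat1 stood apart, was not separated from age for this peak. Ribosomal protein genes declined with age, 74 of 78 falling from E11 to E16 (74 adjusted over the list alone; median -1.28, adjusted p = 1.18e-27, adjusted p = 0.276 with an estimated correlation). Of 12 neutrophil genes 11 rose and 1 fell at E16 against E11 (the same adjusted over the list alone; median 12.05, or 8.82 at the bounds, adjusted p = 6.95e-08, adjusted p = 0.154 with an estimated correlation).

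Among the day 8 cells, 3 clusters outside the secretory class carried secretory transcripts. Free RNA in the droplets as the whole source is argued against, since the lowest of these clusters held 17455 CPM of secretory markers against 15585 in empty droplets, or 1.11 times as much at the counting limits, and free RNA alone cannot exceed its own level. A part from free RNA stays open. Droplets with 2 cells may account for them and stay open: 0.118% of their genes at 50 CPM or more (4 of 3402) lay at least 1.5-fold above every named cluster, against 0.0366 to 11.96% for the other clusters, and their median doublet scores were at least 0.0912 against at most 0.0615 elsewhere. These clusters hold 19.7% of the cells, where the doublet search assumed 0.05 of them. Cells passing from a cycling to a secretory state are a biological alternative that stays open for 2 of the clusters, since it was not tested. The smallest cluster held medians of 6 cell cycle, 904.5 colonocyte and 1523 secretory UMIs per cell, so such a change of state does not account for its colonocyte transcripts. Without these clusters, secretory-like cells made up 29.0% of the rest.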
